A study of Caenorhabditis elegans with 2 samples.

How the data were processed

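Peak lists of TBX-37 chromatin immunoprecipitation were taken as deposited, for 2 biological replicates of whole early embryos in 1 group. Per the labels, the replicates are separate biological replicates of one tagged strain, chromatin was sheared by sonication, and the build is ce11. Per the text files deposited beside the lists, peaks were derived from aligned reads of the precipitation and of a control, and the thresholded lists also from a further file. The aligner, the peak caller and their versions are not given in the sources used here. The control experiment that the labels list, and that further file, were not used here.

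The deposited lists are of 2 kinds. Ranked lists hold all candidates that entered a comparison by irreproducible discovery rate (IDR). Thresholded lists hold those that passed, except for some that they leave out (205 for the conservative list). The conservative list was made by the authors from both replicates, and its peaks are a subset of 66355 ranked candidates. The other series-wide list (1042 peaks of 41925 candidates) comes from parts of the pooled reads, and each replicate also has its own list, made by the authors from its reads alone (538 peaks of 39578 candidates for replicate 1 and 817 of 44219 for replicate 2). The conservative list and the other series-wide list share 897 identical regions. The score of each deposited peak is the authors' IDR on a scale with a maximum of 1000, a value reached by 871 conservative peaks. The lowest score in the thresholded lists corresponds to an IDR close to 0.01. The signal value of a peak is the score the authors' peak caller wrote. Since its scale differs between the lists of the replicates, levels were described, ranked and tested only within a list. The correlation between the replicates was the single comparison between lists. The −log10 of the IDR in the deposited ranked lists was used for candidates below the threshold. The summit offset that the authors gave for each peak set its position. The ranked list of the replicates has 8 further per-sample columns that could not be tied to a replicate by name and were not used. No read counts are in the lists, so the depth per replicate is unknown and binomial intervals cover counting error over peaks only. Nearby peaks are not independent, and p-values over peaks do not measure the spread between embryos.

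Genes and sequence came from the WBcel235 genome with Ensembl annotation release 115, whose chromosomes are those of ce11. A summit was assigned to the nearest of 19973 protein-coding gene starts within 5000 bp. Location classes were taken in the order promoter (1000 bp upstream to 200 bp downstream of a start), untranslated region, coding exon, intron, downstream and intergenic. The downstream class, within 1000 bp past a gene end, had no place in the class order fixed beforehand and was put after introns. Location was tested against 1000 circular shifts of the summits within chromosomes, gene lists with Fisher's exact test against all other protein-coding genes, motifs and words with an exact McNemar test of the summit window (100 bp each side) against flanks 500 bp away, taking the larger p of both sides, signal values with 100000 permutations, and chromosomes with exact binomial tests. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Small RNA genes within 100 bp of a summit were counted after the data had been seen. Fixed gene lists, motifs, tests and most alternatives were written before the data were examined. In the 24 lists, tbx-42, elt-5 and opt-2 matched no gene symbol of the annotation.

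Named genes followed a rule: tbx-37, tbx-38 and lsy-6 whatever their values, the 20 strongest peaks with an assigned gene, the 4 strongest members of each list with a peak, and the 5 strongest peaks of each replicate without a partner in the other. Members beyond these that are named where a count is 6 or fewer, the 4 peaks with AGGTGTGA, and the small RNA genes were chosen after their values had been seen.

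Alternatives were the other series-wide list, an IDR of 0.01, each replicate's own list, other promoter widths (500 and 2000 bp) and peak midpoints, other gene assignments (2000 bp), a stratified and a shifted background, other motif windows (50 and 200 bp) and flanks (1000 bp), 200 dinucleotide-preserving shuffles, a reciprocal overlap of 50%, summits within 100 bp, equal numbers of peaks, expectation by gene number and a narrower centre. After seeing the data, peaks with the highest score alone and peaks away from tRNA genes were added, the latter also with expectation by gene number. Copies of sequence were counted as words of 36 bases found more than once in the genome, and 20000 windows matched in GC content within 1 percentage point were drawn.

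The scripts were tested on simulated data with fixed seeds before use. With summits placed at random, 0 of 24 lists, 0 of 12 motifs, 0 of 2080 words and 0 of 6 chromosomes passed. With 50% of the summits planted at promoters and the rest placed at random, the promoter share came out at 60.3% where 60.6% was expected. Of shared peaks 301 were found where 300 were planted, and a planted log2 difference of 0.50 was estimated as 0.56. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.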

Results

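Chromatin immunoprecipitation followed by sequencing was used to map binding of TBX-37, a T-box transcription factor, in whole early embryos of the nematode Caenorhabditis elegans. TBX-37 and its close paralog TBX-38 act in descendants of the ABa blastomere, where they are needed for the anterior pharynx and for an early mark on the microRNA gene lsy-6 in a lineage that makes a taste neuron. The endogenous tbx-37 gene carried an inserted green fluorescent protein tag, and an antibody against the tag was used for the precipitation. The samples formed 1 group of 2 biological replicates, collected at 0 hours as eggs freed by bleaching. With 1 group there was no contrast between conditions, and the comparisons were those within the peak lists: between the replicates, between peaks and shifted positions, and between peak summits and their flanks. The files listed peaks without read counts, so the depth of each replicate is unknown. The conservative list, made by comparing both replicates, held 1107 peaks with a median width of 256 bp and was used for all results unless another list is named. The list made from replicate 1 alone held 538 peaks and that from replicate 2 alone 817. Signal values are the authors' own value for each peak, their levels were compared only within a list, with a correlation as the single comparison between lists, and they ran from 3.30 to 794 with a median of 104 in the conservative list. Coordinates are 1-based and refer to ce11, which is the WBcel235 assembly.

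The locus of the tagged gene held no peak. The nearest peak to tbx-37 (III:11224808–11227125, minus strand) lay 59158 bp away at III:11286155–11286410 in the conservative list and at a similar distance in the lists of replicate 1 (59143 bp) and replicate 2 (59154 bp). Below the threshold, the strongest candidate within 5000 bp of tbx-37 had a signal value of 40.8, an irreproducible discovery rate (IDR) of 0.576 and rank 10027. At the paralog tbx-38 (III:11784082–11786061, minus strand) the nearest conservative peak lay 6727 bp away at III:11792660–11792915, with a signal value of 91.1. The nearest peak to tbx-38 lay 6727 bp away in the list of replicate 1 and 37153 bp away in that of replicate 2. A candidate 352 bp upstream of tbx-38, at III:11786285–11786540, had a signal value of 62.7 and ranked 1816, and its IDR of 0.0315 did not pass the lists' threshold. The microRNA gene lsy-6 (V:10647232–10647304, plus strand) had its nearest conservative peak 68097 bp away, and the nearest peaks in the lists of replicate 1 and replicate 2 lay 89647 bp and 121123 bp away. The strongest candidate within 5000 bp of lsy-6 had an IDR of 0.744.

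Many of the strongest peaks lay at genes for small structural RNAs. The peak with the highest signal value, 794, was at V:12303505–12303764 in an intron beside the small nucleolar RNA (snoRNA) gene C51F7.4, with F55C5.17 as the nearest protein-coding start. Next came a peak at the snoRNA gene W03C9.9 near W03C9.1 (signal value 789, II:11960690–11960952) and a peak 523 bp upstream of K12H4.5 (745, III:8043860–8044075), which had no small RNA gene beside it. Further snoRNA genes lay under the peaks assigned to the chemoreceptor genes str-56 (631) and sre-23 (605), the cuticlin-like gene cutl-18 (620), T02E1.2 (428), the potassium channel gene twk-5 (403) and Y43F8C.7 (370). Transfer RNA (tRNA) genes lay under the peaks of the collagen genes col-181 (475) and col-85 (390), C04A11.5 (447), the cyclin E gene cye-1 (418), lev-9 (417), C28G1.2 (408), the guanylyl cyclase gene gcy-33 (390), pgl-2 (377) and F28H6.7 (376). The peak assigned to hrg-5 (468) lay at the microRNA gene mir-51, and the peak 173 bp upstream of T13C5.6 (385) lay at none. Of these 20 strongest peaks with an assigned gene, 9 were at tRNA genes, 8 at snoRNA genes, 1 at a microRNA gene and 2 at no small RNA gene, and 4 stronger peaks without an assigned gene were passed over. Counted with or without an assigned gene, 15 of the strongest 50 peaks and 35 of the strongest 100 lay at no small RNA gene. All 20 named peaks were also in the own list of each replicate.

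Across the whole list, tRNA genes were the largest small RNA class at peaks. A tRNA gene lay within 100 bp of 232 of the 1107 summits (21.0%, exact 95% binomial interval 18.6 to 23.5), against a mean of 1.97 ± 1.42 summits (SD) in 1000 circular shifts of the summits along their chromosomes. These summits covered 235 of the 612 annotated tRNA genes (38.4%). The snoRNA genes accounted for 56 summits (5.06%, interval 3.84 to 6.52) against 1.34 ± 1.17 after shifting. Small nuclear RNA genes, among them the SL2 spliced leader genes sls-2.1, sls-2.2 and sls-2.4, accounted for 9 summits against 0.408 ± 0.632. A two-sided permutation test by shifts of tRNA, snoRNA and small nuclear RNA genes gave p = 0.002, the smallest that the shifts can give, for each class, with an adjusted p of 0.00333 over 5 classes. MicroRNA genes had 3 summits, at mir-51, mir-52 and mir-5549 (shift permutation p = 0.0879, adjusted p = 0.110), and ribosomal RNA genes had 0, which allows a share of up to 0.333%. Peaks at tRNA genes had a median signal value of 141 against 97.0 for all other peaks, a difference of 0.52 ± 0.06 in mean log2 signal (SE), and those at snoRNA genes 211 against 101, a difference of 0.95 ± 0.13. This count of small RNA genes was added after the strongest peaks had been seen, and the differences in signal are given without a test because these classes were picked from the strongest peaks.

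Peaks gathered at promoters and were scarce in coding exons. Promoters, taken as 1000 bp upstream to 200 bp downstream of a protein-coding gene start, held 587 summits (53.0%, interval 50.04 to 56.0), against 21.0 ± 1.23% (SD) of shifted summits. Coding exons held 25 summits (2.26% against 19.5 ± 1.23%) and untranslated regions 12 (1.08% against 3.47 ± 0.55%). Introns held 251 summits (22.7% against 31.2 ± 1.42%) and intergenic sequence 154 (13.9% against 19.1 ± 1.33%). Each of these classes gave p = 0.002 in the same shift permutation test, the smallest the shifts can give, and an adjusted p of 0.0024 over 6 classes. The sequence within 1000 bp past gene ends held 78 summits (7.05% against 5.60 ± 0.70%), which missed the threshold of that permutation test (adjusted p = 0.0539). A gene start lay within 500 bp of 523 summits (47.2%). Promoter peaks had a median signal value of 106 and other peaks 101, and mean log2 signal differed by -0.08 ± 0.05 (SE, permutation p = 0.151). The difference passed as -0.17 (permutation p = 0.00107) in the own list of replicate 1, -0.12 (0.0236) in that of replicate 2 and -0.22 (2e-05) among peaks with the highest score. In the conservative list the difference turned to 0.13 with permutation p = 0.0435 when the peaks at tRNA genes were left out. This alternative and the highest score were chosen after seeing the data.

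**Figure D1:**
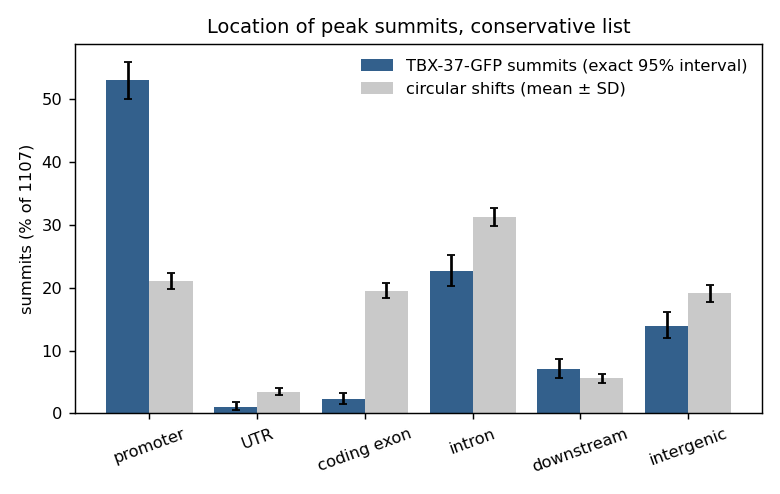
Share of the 1107 conservative peak summits (vertical axis, percent) in each annotation class, with exact 95% binomial intervals, beside the mean and SD of circularly shifted summits. Promoters hold 53.0% of summits against 21.0% after shifting, and coding exons 2.26% against 19.5%.

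In the conservative list, genes for ribosomal proteins, cell cycle regulators and histones carried peaks more often than other genes, and chemoreceptor and F-box genes less often. The 1005 peaks within 5000 bp of a start were assigned to 937 of 19973 protein-coding genes (4.69%), and 5 of 24 fixed gene lists differed from all other genes. Among ribosomal protein genes 16 of 78 had a peak (20.5%, interval 12.2 to 31.2), and all 16 of those peaks were at promoters. They included rpl-3 (signal value 267, III:3867518–3867641), rpl-15 (252, IV:654871–655000), rpl-35 (160, III:7854576–7854831) and rps-28 (149, IV:1659111–1659366). Among cell cycle genes 6 of 28 had a peak (21.4%, interval 8.30 to 40.95): cye-1 (418), whose peak lay at a tRNA gene in its intron, the retinoblastoma homolog lin-35 (108), the cyclin A gene cya-1 (89.2), the spindle checkpoint gene bub-1 (74.6), fzr-1 and wee-1.3. Among histone genes 8 of 59 had a peak (13.6%, interval 6.04 to 24.98), including the linker histone gene hil-3 (294), whose peak lay at a tRNA gene 2978 bp upstream of its start, and the promoters of his-5 (127), his-64 (100.3) and his-37 (87.8).

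The chemoreceptor genes, which encode receptors of sensory neurons, had a peak at 14 of 1299 members (1.08%, interval 0.590 to 1.80). Of those 14 peaks 6 were at tRNA genes and 2 at snoRNA genes, and the strongest were assigned to str-56, sre-23, srd-43 (306) and sre-20 (304). The F-box families fbxa, fbxb and fbxc had 3 of 315 (0.952%, interval 0.197 to 2.76), at fbxb-85 (157), fbxb-58 (112) and fbxa-190 (65.8). Fisher's exact tests, two-sided, gave odds ratios of 5.32 for ribosomal proteins (adjusted p = 6.5e-06 over 24 lists), 5.57 for the cell cycle (0.00976), 3.21 for histones (0.0290), 0.210 for chemoreceptors (2.2e-12) and 0.193 for F-box genes (0.00306). The histone call of the exact test ended in the other series-wide list (odds ratio 2.90, adjusted p = 0.0744), when genes were stratified by upstream distance (2.71, 0.0750) and in the own list of replicate 2 (odds ratio 2.52, 0.352), and its direction turned in that of replicate 1 (odds ratio 0.724, adjusted p = 1). With every start within 2000 bp counted, the histone odds ratio was 8.11 (21 of 59 genes), where 1 peak can count for several neighbouring genes. With shifted peaks as background, 8 histone genes stood against a mean of 1.13. That is a ratio of counts of 7.05, which is not comparable with the odds ratios. The cell cycle call of the exact test ended in the own lists of replicate 1 (odds ratio 3.24, adjusted p = 0.824) and replicate 2 (3.26, 0.367), with a smaller odds ratio. The F-box call ended there too (0.265, adjusted p = 0.300, and 0.257, 0.0653, exact tests). With shifted peaks as background it also ended, at 3 genes against a mean of 10.8, a ratio of counts of 0.277 (shift permutation, adjusted p = 0.125). By that background the ratio of counts was 0.370 for chemoreceptors and 8.08 for ribosomal proteins, and both calls held (shift permutation, adjusted p = 0.0120). Among the 871 peaks with the highest score the cell cycle (odds ratio 4.23) and histone (2.88) calls ended as well (adjusted p = 0.116 for both exact tests).

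**Figure D2:**
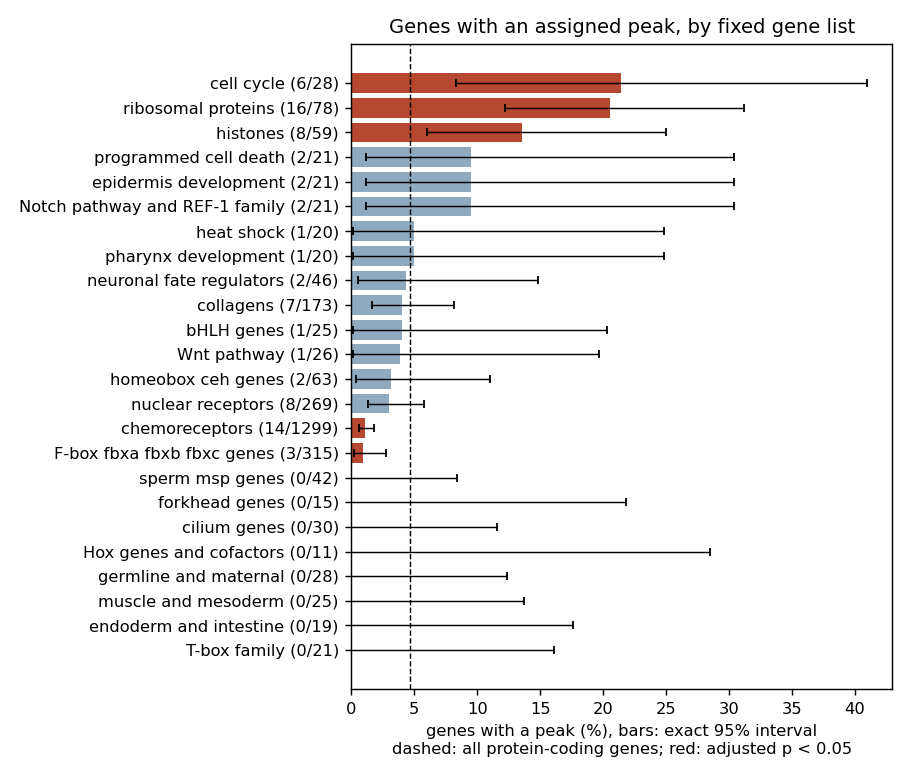
Share of protein-coding genes with an assigned peak (horizontal axis, percent) in each of 24 fixed gene lists, with exact 95% binomial intervals and the number of genes with a peak over the number of members. The dashed line marks 4.69% of all protein-coding genes, red bars mark adjusted p under 0.05, and 8 lists have no member with a peak.

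The lists of developmental regulators did not differ from other genes in the same test. No peak was assigned to any of 21 T-box genes, 19 endoderm and intestine genes, 25 muscle and mesoderm genes, 28 germline and maternal genes, 11 Hox genes and cofactors, 30 cilium genes, 15 forkhead genes or 42 sperm msp genes. For lists of this size a count of 0 leaves shares of up to 8.41% (sperm msp genes) to 28.5% (Hox genes and cofactors) inside the exact interval, with 16.1% for the T-box genes. Of 21 genes of the Notch pathway and REF-1 family, through which the embryo sets apart the ABa and ABp lineages, hlh-29 (89.7, 2937 bp past its start) and the presenilin gene sel-12 (78.7, promoter) had a peak. The homeobox gene ceh-2 (80.9) was the single pharynx gene of 20 with a peak, which lay at a tRNA gene. Neuronal fate regulators had 2 of 46, lin-32 (168, at a tRNA gene) and lim-6 (103), and epidermis genes 2 of 21, dlg-1 (88.0) and elt-6 (68.1). The Wnt pathway had 1 of 26, the beta-catenin gene wrm-1 (70.4), and programmed cell death 2 of 21, the engulfment gene ced-5 (216, promoter) and lin-35. Among gene families, 8 of 269 nuclear receptors (strongest nhr-277, 329), 2 of 63 ceh homeobox genes (ceh-45 and ceh-2), 1 of 25 bHLH genes (hlh-29), 7 of 173 collagens (col-181, col-85, col-99 and col-94 the strongest) and 1 of 20 heat shock genes (hsp-3, 102) had a peak. Adjusted p-values of these 19 lists ran from 0.637 to 1. With every start within 2000 bp counted, the nuclear receptors passed as well, below other genes (5 of 269, odds ratio 0.271, exact test, adjusted p = 0.00313).

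Most peaks of replicate 1 were found again in replicate 2. A replicate 2 peak overlapped 451 of the 538 replicate 1 peaks by at least 1 bp (83.8%, interval 80.4 to 86.8), against 2.04 ± 3.14 (SD) after circular shifts (one-sided permutation p = 0.001, the smallest the shifts can give). In the other direction 452 of 817 replicate 2 peaks (55.3%, interval 51.8 to 58.8) overlapped a replicate 1 peak. Across the 451 shared peaks log2 signal values had a Spearman rho of 0.785 and a Pearson r of 0.829, where peaks are not independent replicates and no p is given. Of the 1107 conservative peaks, 453 (40.9%) overlapped a peak in both own lists and 345 (31.2%) overlapped a peak in neither. The 87 peaks found in replicate 1 alone had a median signal value of 44.3 against 66.8 for shared ones, and 78 of them overlapped a candidate below the threshold in replicate 2. For the 365 peaks found in replicate 2 alone the medians were 62.3 and 107.6, and 331 overlapped such a candidate. The strongest in replicate 1 alone were assigned to or nearest Y106G6H.9 (100.5), K08F11.1 (75.7), R07H5.16 (72.3), W01D2.3 (67.2) and the mitochondrial import gene tomm-20 (59.8). In replicate 2 alone they were those of the neuropeptide gene flp-23 (138, at a tRNA gene), the CBP homolog cbp-1 (127), the nuclear pore gene npp-18 (122), ZC449.1 (119, at a tRNA gene) and Y32F6A.5 (117).

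**Figure D3:**
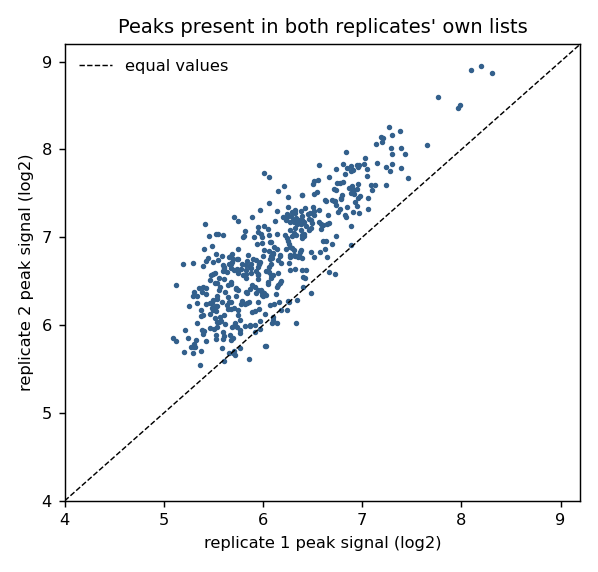
Log2 signal value of each of 451 peaks shared by the own lists, replicate 1 on the horizontal axis and replicate 2 on the vertical axis, with a dashed line of equal values. Each point is a peak, Spearman's rho is 0.785, and the position of points relative to the line carries no meaning of level, since signal values of the lists are on different scales.

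The exact T-box consensus was rare at summits. AGGTGTGA, a consensus sequence for T-box proteins, which also bind variants and paired sites not searched here, lay within 100 bp of 4 of 1107 summits (0.361%, interval 0.0985 to 0.923) and in 0.181% of flanking windows centred 500 bp away (exact McNemar test, p = 1). Those 4 peaks were assigned to lact-7 (229) and srd-44 (101.4), both at tRNA genes, Y18H1A.15 (89.4) and the actin gene act-4 (74.3). The shorter core GGTGTG lay at 79 summits (7.14%, interval 5.69 to 8.82) against 4.43% of flanks (exact McNemar test, adjusted p = 0.0163 over 12 motifs), but dinucleotide-shuffled summit windows held it in 7.18 ± 0.68% (SD) of cases (p = 1). Signal values did not separate peaks with AGGTGTGA from the rest (difference in mean log2 signal -0.01 ± 0.36, SE, permutation p = 0.981).

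Other sequences set summits apart from flanks. GAGAGA lay at 284 summits (25.7% against 11.3% of flanks, exact McNemar test, adjusted p = 7.5e-17) and the GC box GGGCGG at 134 (12.1% against 3.39%, 7.1e-13), and both also exceeded shuffled windows (10.8% and 6.89%, adjusted p = 0.0398 over 12 motifs from 200 shuffles, the smallest p of which is 0.00995). Motifs of GATA factors (33.5% against 44.9%, 1.5e-07), the Wnt effector TCF (8.67% against 14.6%, 7.0e-05), SKN-1 (4.79% against 9.71%, 5.3e-05) and homeodomain proteins (6.41% against 10.2%, 0.00561) were less frequent at summits. Of these, TCF alone was also below shuffled windows (16.4%, permutation test by shuffling, adjusted p = 0.0398), where GATA (36.2%), SKN-1 (5.56%) and homeodomain (5.80%) motifs did not pass. LAG-1, forkhead and E-box motifs and the reversed control AGTGTGGA did not pass against flanks (adjusted p from 0.498 to 1). The reversed control lay at 11 summits (0.994% against 0.407% of flanks), more than the 4 with AGGTGTGA. Summit windows had a GC content of 44.1% and flanks 36.9%.

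In a scan of all 2080 words of 6 bases, 807 differed between summits and flanks, 427 of them more frequent at summits, and 492 differed in the shorter own list of replicate 1. The first was CGGCCA, at 211 summits (19.1% against 3.21% of flanks, exact McNemar test, adjusted p = 1.3e-30), followed among enriched words by CGCGCA at 177 (15.99% against 2.48%, 6.1e-26). CGAACC (18.3% against 3.88%, 5.9e-25) and GTTCGA (24.0% against 8.36%, 1.2e-19) are parts of the B box, the internal promoter element of tRNA genes. Among the 875 peaks away from tRNA genes CGCGCA came first, at 173 summits (19.8% against 2.29%, 2.4e-29). The T-box core, in its other orientation CACACC, ranked 713. The words were not set against shuffled windows. The higher GC content of summits (44.1% against 36.9% in flanks) may therefore account for part of the 807 differences.

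Chromosomes I and III carried more peaks than their length predicts and chromosome V fewer. Chromosome I held 205 peaks (18.5%, interval 16.3 to 20.9, 1.23 times its share of the length) and III held 188 (16.98%, 14.8 to 19.3, 1.24 times), both with an adjusted p of 0.00447 in exact binomial tests. Chromosome V, rich in chemoreceptor genes, held 156 (14.1%, 12.1 to 16.3, 0.675 times, 5.3e-08). Chromosome II (164 peaks, 0.972 times, 0.738) and IV (169, 0.875 times, 0.0687) did not pass. The X chromosome held 225 peaks (20.3%, 17.99 to 22.8) against 17.7% of the length (1.15 times, 0.0334), and 99 of them lay at tRNA genes, of which X carries 276 of 612 (45.1%). Without the peaks at tRNA genes X held 126 of 875 peaks (14.4%, 0.815 times, 0.0152), below its share of the length. Against its share of protein-coding genes X held 1.49 times as many peaks (exact binomial adjusted p = 3.9e-09), and 1.05 times (0.522) without those at tRNA genes, which were left out after seeing the data. By that expectation chromosome II with all its peaks fell below its share (0.858 times, exact binomial adjusted p = 0.0380). By length, the call for X ended in the shorter own lists of replicate 1 (1.14 times, exact binomial adjusted p = 0.170) and replicate 2 (1.16 times, 0.0869) and among the 871 peaks with the highest score (1.16 times, 0.0588) at ratios close to that of the full list. The call for III ended in the list of replicate 1 (1.26 times, exact binomial adjusted p = 0.0610) without a smaller ratio. The call for I ended in all 3 with smaller ratios (1.17 times, 0.137, 1.13 times, 0.176, and 1.12 times, 0.232, in the same exact tests). The middle 50% of the chromosomes held 605 peaks (54.7%, interval 51.7 to 57.6, exact binomial p = 0.00216), and the excess lay on V (66.7%, p = 3.8e-05) and II (61.0%, 0.00610). On I (50.7%), III (53.2%), IV (52.1%) and X (48.4%) the share did not pass (exact binomial p from 0.422 to 0.889). The centre tests of single chromosomes were not in the plan, and their p-values are unadjusted. The expected 50% follows from length alone, and an expectation by gene number was not tested for the centre. With a narrower centre the pooled call ended (35.7%, exact binomial p = 0.0975).

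**Figure D4:**
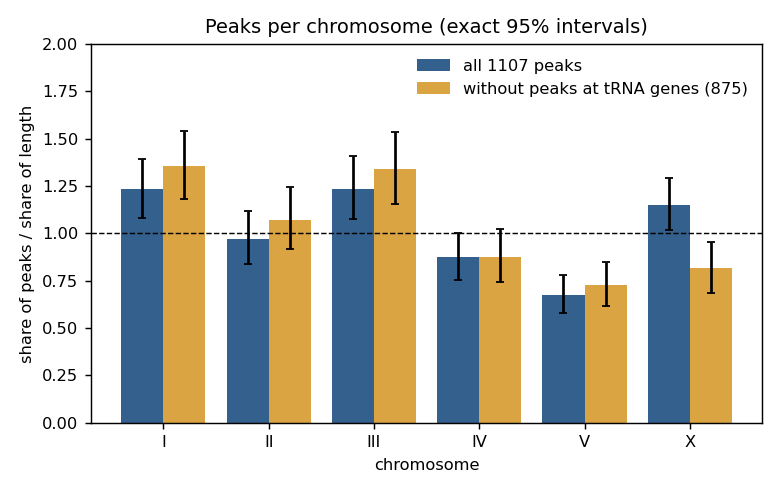
Share of peaks divided by share of the genome length for each chromosome (vertical axis, ratio), with exact 95% binomial intervals, for all 1107 peaks and for the 875 away from tRNA genes. The dashed line marks a ratio of 1, and X lies at 1.15 with all peaks and at 0.815 without those at tRNA genes.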

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

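The test of removal by strength alone was chosen after the result had been seen, and the tests of fixed regions and of repeated sequence were not.

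The conservative list leaves out 205 candidates whose score is at or past its own lowest score, a signal in data that the comparisons above do not use. The highest signal value among them was 4690, at X:15810947–15811201, against 794 for the strongest peak kept, and the 22 strongest of all candidates were left out. Of the 205, 8 (3.90%) lay at promoters and 1 at a tRNA gene. Removal by strength alone is argued against, since 24.9% of the candidates left out had a signal value below the median of those kept. Removal of fixed regions by the authors met its prediction: 0 of 346 candidates left out of one replicate's list overlapped a candidate kept in the other's, and 293 (84.7%) overlapped one also left out. Sequence present in several copies also met its prediction, with mostly repeated summit windows in 91.2% of those left out against 7.77% of those kept (Fisher's exact test, p = 3.9e-135). A candidate explanation is therefore a list of repeated regions that the authors removed. The design gives no second group, and no biological explanation was tested.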

How the results depend on the processing

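The alternatives that kept peaks with the highest score alone or left out peaks at tRNA genes, with either expectation, were chosen after seeing the data. Of 155 alternative values 114 were called the same, 10 reversed, 19 became weaker, 5 stronger and 7 moved. A test was called the same if it kept direction and side of the threshold. Counts of lists, chromosomes and words were called the same within a set factor of the main count, and moved beyond it. By this rule 587 words against 807 were the same. The correlation was called the same if it shifted by less than its error over resampled peaks. An IDR of 0.01 removed no peak, says nothing on stability and is left out of these counts (21 values), and motif against strength gave no value without replicate 2, where 1 peak held the motif. Lists past the threshold numbered 5 in the conservative list, 4 in the other series-wide list, with stratification and with shifts, 6 with every start within 2000 bp (nuclear receptors added), 2 in the own list of either replicate and 3 at the highest score, and the histone odds ratio ranged from 0.724 to 2.52 without a replicate. Words past the threshold numbered 492 to 698 without a replicate. Shorter lists explain part of such losses by construction, since fewer peaks are tested. The share with AGGTGTGA was 0.186% to 0.367% without a replicate, no longer above flanks at the lower value, 0.542% and below flanks with 200 bp windows, and at 0.361% below shuffled windows. The core GGTGTG gave 7.14% and passed against flanks, but shuffled windows held it in 7.18% of cases. The promoter difference in log2 signal was -0.17 to -0.12 without a replicate and -0.22 at the highest score, past the threshold. In the conservative list it was -0.08 with all peaks and 0.13 without those at tRNA genes, so its direction there depended on tRNA peaks. The lists in which the negative difference passed were not tested without those peaks. Chromosomes past the threshold numbered 1 to 2 without a replicate and 2 at the highest score. By number of genes 5 chromosomes passed, among them II at 0.858 (adjusted p = 0.0380, exact binomial) and X at 1.49, and 3 without peaks at tRNA genes, with X at 1.05. By length the ratio of chromosome II did not pass and was 1.01 in the other series-wide list, 0.980 to 1.02 without a replicate, 1.05 at the highest score and 1.07 without peaks at tRNA genes, where X fell to 0.815. A narrower centre held 35.7% of peaks (exact binomial p = 0.0975). For the other changes the cause was not tested. The unknown depth of the replicates limits what the shorter lists can show.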

Other observations

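The tests of tRNA genes on X and of the T-box core by rank, in all ranges, and the count of mostly repeated windows at tRNA genes, were chosen after the results had been seen.

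Away from small RNA genes, most peaks lay at promoters. Of the 807 peaks with no small RNA gene within 100 bp, 519 (64.3%) were at promoters, and so were 12 of the 20 strongest. These 12 were K12H4.5, T13C5.6, T07F10.3, K10D2.5, M01F1.9, the ataxin homolog atx-2 (signal value 363, 74 bp from the start), cux-7 (360), the cyclophilin gene cyn-10 (349), the mitochondrial gene atad-3 (348), the glutamyl-tRNA synthetase gene ears-2 (342), the prefoldin gene pfd-5 (310) and the isocitrate dehydrogenase gene idhg-1 (302). The other 8 lay elsewhere, such as those nearest the starts of nhr-277 (329, intergenic), ccm-2 (324, intron) and ints-8 (295, intron). The ccm-2 peak lay 3240 bp upstream of the gene's start, so that intron is not one of ccm-2. The ints-8 peak lay 6395 bp past the gene's start, beyond the distance limit for assigning a gene. This set of peaks without small RNA genes was picked after its values had been seen, and no list of functions was tested on it.

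The gathering of peaks at tRNA genes was set against 3 explanations. GC content is argued against as the whole cause: windows of matched GC content held a summit in 0.715% of cases (interval 0.603 to 0.842), against 38.4% of tRNA genes. Reads shared between copies met both predictions and stay open. The tRNA genes of unique sequence held a summit less often than repeated ones (24.3% against 42.6%, Fisher's exact p = 7.3e-05). Of the 34 unique ones with a summit, 100% held a repeated word of 36 bases, against 76.4% of those without (Fisher's exact p = 0.000583). Of 232 windows at tRNA genes 0 were mostly repeated, but this count cannot decide. A window spans 100 bp on each side of the summit, so repeated sequence confined to a tRNA gene may not fill most of it. Binding through the T-box sequence cannot be told apart from its absence here, as the core lay at 5.53% of tRNA genes with a summit and 3.98% of those without (Fisher's exact p = 0.428). Signal at open or highly transcribed chromatin that does not need TBX-37 was not tested, because the control was not used here.

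The excess of peaks on X may follow from its tRNA genes. Without peaks at tRNA genes the share on X was 14.4%, below its 17.7% of the length and 1.05 times its share of protein-coding genes (exact binomial adjusted p = 0.522), against 1.15 and 1.49 times with all peaks. The excess over either expectation thus ended, and a deficit passed against length alone. A biological difference of X was not tested.

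The hypothesis that weaker candidates hold the T-box sequence more often than the strongest was tested on the ranked candidates. The core GGTGTG lay at 9.9% of candidates ranked after 1000 and up to 2000 against 4.0% of the first 500 (Fisher's exact p = 4.2e-05), and at 10.2% against 4.62% once left-out candidates and those at small RNA genes were removed (p = 0.0137). That range of ranks was chosen after results had been seen and holds the highest share of all ranges counted. Every later range held a higher share than the first 500, and beside the chosen range the ranks after 2000 up to 4000 (9.35%, Fisher's exact adjusted p = 0.000147 over 7 ranges), the next up to 8000 (7.4%, 0.00900) and the next up to 16000 (6.83%, 0.0214) passed. The ranks after 500 up to 1000 (7.0%, 0.0598), those after 16000 up to 32000 (6.24%, 0.0529) and the weakest (5.31%, 0.226) did not. All 7 comparisons share the first 500 as reference and are not independent, since a low share there raises them together. Of those 500, 195 remained once left-out candidates and those at small RNA genes were removed, against 918 of 1000 in the chosen range. The other ranges were not tested after that removal. Their passes therefore cannot be told apart from an effect of such candidates in the first 500. All ranks after the first 500 together, of which the weakest range makes up 34355 of 65855, held the core in 6.05% of cases (Fisher's exact p = 0.0587). The reversed core GTGTGG rose too, from 6.8% to 10.5% in the chosen range (Fisher's exact p = 0.0231, adjusted p = 0.161 over 7 ranges). It was also higher after 500 up to 1000 (8.0%), after 2000 up to 4000 (9.6%) and up to 8000 (8.43%), and passed in no range. After 8000 it was no higher than in the first 500 (6.8%, 6.29% and 5.66%), while the core shares there stayed above 4.0%. The GC content of summit windows was 42.3% in the first 500. It was 43.4% after 500 up to 1000, 44.1% in the chosen range, 42.7% after 2000 up to 4000 and 41.3% up to 8000. Base composition may thus contribute at ranks up to 4000. After 4000 a higher GC content cannot account for the higher core shares, since GC content there was below that of the first 500. The hypothesis stays open. The difference between the words was not tested.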
